A study of Drosophila melanogaster with 6 samples.

How the data were processed

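Messenger RNA was measured in male Drosophila melanogaster of the Dahomey wild-type strain that had been kept with rival males for 2 or 26 h. Per the labels' protocols, flies were snap frozen and divided into abdomen or head plus thorax, RNA was extracted from pools of 40 male body parts, and single-end reads of 50 nt were sequenced on an Illumina HiSeq instrument. There were 3 pools: abdomen at 2 h, head-thorax at 2 h and head-thorax at 26 h. Each pool was divided into 2 technical libraries, called here split library 1 and split library 2, which per the series design went on separate lanes of 1 flow cell. The undivided libraries of the same pools belong to another series and are not analysed here.

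The deposited files hold whole-number read counts per FlyBase gene identifier, without normalization, and list a gene only when it has at least 1 count. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here. Total counts ranged from 21070598 to 34217543 per library. The files name 16942 genes, of which 16735 matched a symbol in the Ensembl annotation of BDGP6.54; the other 207 are never named. Positions are those of BDGP6.54 and were used for naming and for overlaps, since the files carry no coordinates.

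How the authors counted was checked from the deposited counts. Among genes nested inside a longer gene and holding at least 20 counts, the host gene had at least as many counts in 99.79% to 99.92% of pairs, on the same strand and on the opposite strand alike. With hosts shuffled, this share was 77.4% to 80.5%. Reads therefore seem to have been counted over whole gene spans, without strand, and once for every gene they overlap. Of the annotated genes, 8062 (48.2%) overlapped another gene, so their values can hold reads of a neighbour, and antisense partners cannot be told apart. A set of 17 genes spread over 5 chromosome arms, among them Snap25, rut, for, mbl and Gprk2, had near-identical counts in every library, within 0.15 on the log2 scale of a common level. This set held 9.4% to 10.0% of the total in abdomen, 6.5% to 6.7% in head-thorax at 2 h and 9.9% to 10.1% at 26 h, and its members' values are not read as those of single genes. Copies of 5S, 5.8S and 18S ribosomal RNA genes had identical or nearly identical counts, so reads were apparently counted at each place they align. A gene is said to have reads of its own when it overlaps no other gene and no other gene has identical counts.

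CPM values were computed here from the counts and the effective library sizes given by trimmed mean of M values (TMM). A CPM is given as the mean ± SD of the 2 split libraries of 1 pool (n = 2), which is technical spread only. Split libraries were compared within each pool by a two-sided exact binomial test per gene over genes with a summed count of at least 10, with Benjamini-Hochberg adjustment and a threshold of 0.05. The squared deviation from the expected split, divided by its binomial variance and averaged over genes, gave the variance relative to counting error, with a 95% interval from resampling genes.

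Pools were compared with edgeR 4.0.16 (quasi-likelihood test, TMM, filterByExpr, all 6 libraries in 1 fit) in R 4.3.3. A gene was called higher or lower at a Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold difference. There is 1 pool per group, so the difference between groups has no biological replicate check. The p-values measure the technical spread between split libraries (3 residual degrees of freedom, a technical coefficient of variation of 1.63%) and compare these pools, not the conditions. Floors and counting intervals cover counting error only, and intervals from resampling genes cover the spread over genes. None covers the variation between pools of flies. Where a pool had 0 counts, the fold is a lower bound against a floor of 3 counts over the pool; with 1 to 3 counts the ratio of pooled CPM is given with its exact counting interval.

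There were 28 gene lists, fixed before the data were examined, as were the tests of the comparisons and the rule for named genes. A list is described by its members that passed and by the percentile of its median log2 ratio among 10000 random lists matched on mean expression, as a description of these libraries with no p-value. In the rule, a comparison names the 10 genes with the largest log2 ratio in each direction among those with adjusted p under 0.05, at least 20 CPM in the higher pool and the same direction in all 4 pairings of split libraries, and up to 4 members of each list with the highest mean CPM. In each pool the 3 genes with the smallest p between split libraries are named. Other genes are named where 5 or fewer members of a group passed, or are singled out, after their values were seen.

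The steps were tested on simulated counts. For the abdomen comparison, 92.4% of 66 genes changed 3-fold and 98.4% of 61 changed 8-fold were called, with 2 false calls among 14342 genes. For the 26 h comparison, 98.4% of 61 and 100% of 83 were called, with 0 false calls among 14318 genes. The simulated libraries shared 1 mean profile and few genes were changed. In the real abdomen comparison 57.35% of genes were called, so these rates do not test its scaling. Of 200 random lists drawn on shuffled ratios of the 26 h comparison, 5.0% had a percentile outside the central 95%. Alternatives were DESeq2 1.42.0 size factors and its Wald test, raw totals, no filter, only the 4 libraries compared, the split number as a block, each library left out, no fold threshold and a fold tested inside the model (glmTreat). Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the remaining steps.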

Results

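The series asked what is gained or lost when a sequenced sample is divided into technical replicates at reduced depth per library. The 6 libraries came from 3 pools of 40 male body parts. Split libraries 1 and 2 held 21070598 and 31276428 counts for abdomen at 2 h, 32627878 and 22604036 for head-thorax at 2 h, and 31203759 and 34217543 for head-thorax at 26 h. Transcripts of the mitochondrial genome took 8.04% and 7.46% of counts in abdomen, 17.3% and 17.9% in head-thorax at 2 h, and 22.0% and 21.6% in head-thorax at 26 h.

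The first comparison asked whether libraries made from 1 pool gave the same gene values. Abundant mitochondrial transcripts had the smallest p between split libraries, a ranking that depends on the count as well as on the size of the difference. The mitochondrial large ribosomal RNA mt:lrRNA and the cytochrome c oxidase subunits mt:CoI and mt:CoIII were the 3 genes with the smallest p in every pool, yet their differences were small. In abdomen, split library 1 was higher by 1.08-fold for mt:lrRNA, 1.09-fold for mt:CoI and 1.09-fold for mt:CoIII. In head-thorax at 2 h split library 2 was higher, by 1.04-fold, 1.05-fold and 1.05-fold. At 26 h split library 1 was higher again, by 1.02-fold, 1.03-fold and 1.04-fold.

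By the exact binomial test, 261 of 14765 genes differed between the abdomen libraries, 76 of 12232 between the 2 h head-thorax libraries and 59 of 12865 between the 26 h head-thorax libraries. Of these genes, 10, 11 and 11 were of the mitochondrial genome, and 234, 48 and 31 were neither mitochondrial nor in the near-identical set. Few of the genes that differed did so over 2-fold: 3 in abdomen, 7 in head-thorax at 2 h and 1 at 26 h. The abdomen genes were spok, ninaE and c(2)M, with ninaE, the major rhodopsin of the eye, at 79 and 52 counts. In head-thorax at 2 h, betaTub85D, a tubulin of the male germline, had 54 counts in split library 1 and 12 in split library 2 (adjusted p = 0.02945, exact binomial test), and CG10252 had 57 and 10. The 26 h gene was lncRNA:CR42839, with 84 and 44 counts. All 17 genes of the near-identical set differed in each pool, in the same direction as the summed mitochondrial coding transcripts, by log2 ratios of 0.08 to 0.10 in abdomen, −0.06 to −0.05 in head-thorax at 2 h and 0.04 at 26 h.

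The variance between split libraries was 2.44 times counting error in abdomen (95% interval 2.05 to 2.97), 1.82 times in head-thorax at 2 h (1.498 to 2.26) and 1.54 times at 26 h (1.36 to 1.79). The excess was largest in abundant genes. Among genes with a summed count of at least 10000 the ratio was 21.8, 10.6 and 7.16, whereas from 10 to 50 counts it was 1.075, 1.175 and 1.101. In abundant genes the median difference was still only 1.03-fold in abdomen, 1.01-fold in head-thorax at 2 h and 1.01-fold at 26 h.

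**Figure D1:**
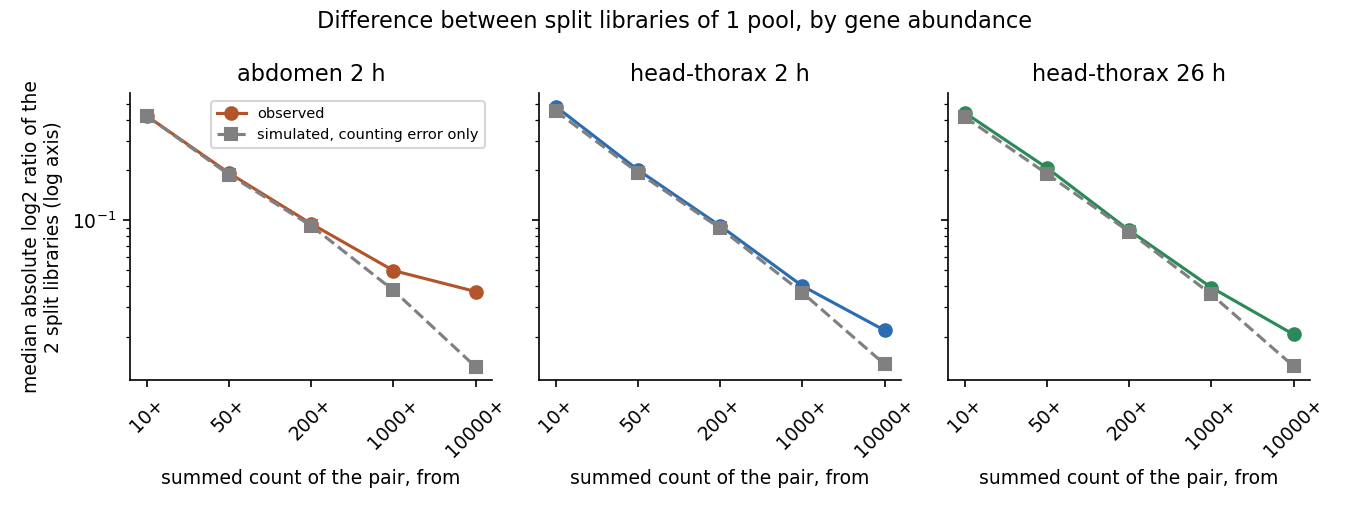
Median absolute log2 ratio of the 2 split libraries (log axis) against the summed count of the pair, for each of the 3 pools, with the value simulated from counting error alone (dashed). The abdomen curve lies slightly above the simulated one from a summed count of 50 (0.192 against 0.188) and more so from 1000 (0.05 against 0.04). The curves part most at 10000 and above, where the abdomen value is 0.04 against a simulated 0.01.

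Splitting cost few detected genes. At 1 count or more, the sum of both libraries held 16381 genes in abdomen, and split libraries 1 and 2 each held 97.3% and 98.5% of them. In head-thorax the shares were 97.1% and 93.9% of 15300 genes at 2 h, and 96.6% and 96.7% of 15426 genes at 26 h. The genes missed by a library had a median summed count of 1. Calls between pools from 1 library per pool were also compared with calls from summed libraries, by the exact binomial test with the 2-fold limit. For abdomen against head-thorax, split libraries 1 and 2 gave 92.2% and 93.3% of 8822 calls. For 26 h against 2 h they gave 65.5% and 60.4% of 1050 calls. No gene was called in opposite directions by this test.

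The next comparison set abdomen against head-thorax at 2 h, the difference between the body parts. Transcripts of the male reproductive organs were the most abdomen-biased group, and those of the eye the most head-biased. The seminal fluid protein Acp36DE reached 2031 ± 39.3 CPM in abdomen against 2.55 ± 0.117 CPM in head-thorax, and Ebp, the ejaculatory bulb protein, 3233 ± 5.12 against 3.24 ± 1.04 CPM. The rhodopsin ninaE stood at 2.41 ± 1.32 CPM in abdomen and 6733 ± 39.5 CPM in head-thorax (SD, n = 2). Of 14694 genes tested by edgeR's quasi-likelihood test, 5233 were higher in abdomen and 3194 lower. Relative to TMM, DESeq2 size factors moved the median log2 ratio of all genes by 0.14 and raw totals by 0.21, so smaller ratios are read against that shift.

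All 54 seminal fluid genes were higher in abdomen, with a median log2 ratio of 9.51, or 9.13 with genes at 0 counts placed at their bound, at percentile 100.0 of matched random lists. In this comparison the number of members passing when adjusted over the list alone equalled that over all genes for each of the 28 lists. In the testis and sperm list 35 of 36 genes were higher (median 8.90, at percentile 100.0), including the sperm leucyl aminopeptidase S-Lap1 (log2 ratio 8.73 ± 0.05 SE). In the ejaculatory duct and bulb list 7 of 9 were higher and 1 was lower (median 9.75, percentile 100.0). The lower member was EbpIII, at 310 CPM in abdomen and 941 CPM in head-thorax.

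The 10 rule-named genes higher in abdomen all had 0 counts in head-thorax. Acp29AB, a seminal fluid protein on chromosome arm 2L, was at 55.6 ± 1.56 CPM in abdomen (SD, n = 2) and at least 995-fold higher. CG31418 was at least 739-fold higher, lncRNA:CR45965 703-fold, CG43254 670-fold, ttm3 611-fold and AttD, an attacin antibacterial peptide, 601-fold, each as a lower bound. The bounds were 576-fold for lncRNA:CR43633, 537-fold for CG15260, 535-fold for CG32117 and 508-fold for CG1138. lncRNA:CR45965 overlaps Ten-m and lncRNA:CR45962, and its reads may not be its own. It had 2309 counts in abdomen, against 2499 for lncRNA:CR45962, which had 113 in head-thorax at 2 h. Ten-m had 7791 counts in head-thorax at 2 h, where lncRNA:CR45965 had 0.

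Of the 10 rule-named genes lower in abdomen, 5 are of the eye, retinin, Xport-A, Xport-B, ninaE and Arr2. alrm, a marker of astrocyte-like glia, and CG9377 had 0 counts in abdomen and were at least 1308-fold and 1064-fold lower. retinin, a protein of the corneal lens, was at 336 ± 1.78 CPM in head-thorax with 4 counts in abdomen. Xport-A and Xport-B, which overlap and act in rhodopsin transport, had 1 count each in abdomen. The head-thorax to abdomen ratio of Xport-B was 4172, with a counting interval from 748.3 to 164800. CG43673, with 2 counts in abdomen, had a ratio of 2662 (736.6 to 21990). The fitted log2 ratios of CG14125, ninaE, CG34324 and the arrestin Arr2 were −11.75, −11.56, −11.26 and −11.21. In the phototransduction list 23 of 29 genes were lower and 0 higher (median −6.81, or −9.87 over 16 with reads of their own, percentile 0.0).

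Neural lists were lower in abdomen. Of 25 synapse and neuron genes 24 were lower (median −3.42, percentile 0.0), with cpx, the SNARE regulator complexin, at −3.36 ± 0.03 SE and nrv3 at −4.12 ± 0.04. Among 26 neuropeptides 21 were lower and 2, Dh31 and CCAP, higher (median −3.94, percentile 0.0). Dh31 overlaps the protease gene Bace, with 37119 counts in abdomen against 37185 for Dh31, so nearly all its abdomen reads can be those of Bace. Of 13 neuropeptides with reads of their own 12 were lower and 0 higher (median −5.22). Of 11 genes of biogenic amine synthesis and transport 10 were lower (median −2.84, percentile 0.0), among them Hn (−1.95) and Ddc (−3.06). Odorant-binding proteins split, with 23 of 40 lower, such as Obp99b (−3.26), and 11 higher, such as Obp56g (3.67), at a median of −1.40 and percentile 0.0. In the small list of chemosensory receptors 4 of 7 were lower, Orco, ppk29, ppk23 and ppk25, and 1, Gr32a, was higher (median −2.20, percentile 0.4).

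Muscle and respiration genes were also lower in abdomen. Of 23 flight muscle sarcomere genes 19 were lower and 1, TpnC47D, was higher (median −1.92, percentile 0.0), with myofilin Mf at −4.04 and arginine kinase Argk1 at −1.74. Of 86 nuclear oxidative phosphorylation genes 63 were lower and 20 higher (median −2.03, percentile 0.0), and the ATP synthase subunits ATPsynbeta and blw were at −2.59 and −1.75. In the mitochondrial genome 22 of 26 genes were lower and 0 higher (median −1.84, percentile 0.0), with mt:CoI at −2.01 ± 0.04 SE. Ribosomal proteins stayed closer together, with 8 of 88 higher and 1, RpL24-like, lower (median −0.22, percentile 79.2).

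Digestive and renal genes leaned to the abdomen. Of 42 midgut enzymes 21 were higher and 3 lower, Jon74E, Mal-A5 and LysP (median 0.94, percentile 100.0), with the maltase Mal-A1 at 1.76 and the amylase Amy-p at −0.87, short of 2-fold. Of 6 Malpighian tubule genes 5 were higher, NaPi-T, Uro, Irk3, ZnT35C and CapaR, and 1, Drip, was lower (median 3.45, percentile 94.1), with urate oxidase Uro at 4.44. Of 39 immune peptides 20 were higher and 10 lower (median 1.46, percentile 99.7, but 0.61 with no filter on low counts and 0.57 over 29 members with reads of their own), with AttC at 6.07 and BomS6 at −1.85. In the cytochrome P450 list 20 of 81 were higher and 16 lower (median −0.01, percentile 52.8, with the sign turning to 0.20 under raw totals). Cyp4g1, an enzyme of cuticular hydrocarbon synthesis, was at 4.18 ± 0.03 SE, and its reads are shared with an overlapping gene. Of 52 cuticle proteins 19 were higher and 26 lower (median −0.996, percentile 0.0), a median that turned to 0.06 with no filter on low counts.

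Several other lists moved in part. The 5 Turandot genes, secreted stress peptides, were all lower in abdomen (median −4.67, or −3.44 with no filter on low counts, percentile 0.0). Of 13 fat body genes 1, tobi, was higher and 5 were lower, Adh, Tsf1, Lsp2, Yp3 and Yp2 (median −0.77, percentile 9.4). Of 11 hemocyte genes 5 were lower, Col4a1, vkg, Pxn, eater and NimC1 (median −0.84, percentile 6.9), and with the fold tested inside the model Col4a1 (−1.02) and eater (−1.01) did not pass. Under raw totals Col4a1 (−0.81), eater (−0.80) and Pxn (−0.91) were short of 2-fold, as were Col4a1 and eater without split library 1 of head-thorax (−0.93 and −0.88), Col4a1 without split library 1 of abdomen (−0.98) and eater without split library 2 of abdomen (−0.91). Of 23 heat shock genes 6 were higher and 9 lower (median −0.15, percentile 58.7, with the sign turning to 0.06 under raw totals), with the chaperonin Hsp60C at 9.36. Of 10 circadian genes 4 were lower, Pdp1, to, vri and per, and 1, Clk, was higher (median −0.63, percentile 22.0). Of 9 activity-regulated genes 5 were lower, kay, CG14186, Hr38, CG17778 and sr, and 1, Arc1, was higher (median −1.49, percentile 0.6). Of 10 sex determination and dosage genes 7 were lower (median −1.36, percentile 0.5), with the male X chromosome RNA lncRNA:roX1 at −1.57. Of 11 nutrient response genes 2 were higher, tobi and Lip3, and 3 lower, Thor, to and Ilp6 (median 0.20, or −0.17 over 6 with reads of their own, percentile 78.4), and Thor (−1.01) did not pass with the fold tested inside the model. Thor was also short of 2-fold under raw totals (−0.80) and without split library 2 of abdomen (−0.98) or split library 1 (−0.98) or 2 (−0.996) of head-thorax. Of 4 measured eggshell genes, not expected in males, 2 were higher (median 2.92, or 2.19 with bounds, 0.61 with no filter on low counts and 0.42 over 3 with reads of their own, percentile 56.2). These 2 were dec, at 1.73 CPM in abdomen, and Cp15, at 0.848 CPM. The ribosomal RNA list (105 of 125 higher, 15 lower, median 2.10, percentile 100.0) consists mostly of gene copies that share reads. Over its 21 members with reads of their own the direction turned, with 8 higher, 8 lower and a median of −0.88. Of the genes named by ratio in this comparison, these overlap another gene and may hold its reads: Acp36DE, CG34324, Arr2, alrm, Lsp2, Mf, Dh31, cpx, ATPsynbeta, AttC, LysP, Mal-A1, Ddc, lncRNA:roX1, Adh, tobi, Drip, RpL24-like, Irk3, Pxn, Lip3, Ilp6, dec, CCAP, Gr32a, ppk25, ppk29, Clk, vri, per, kay, sr and Hr38. The overlapping gene held much of the abdomen count for Clk (CG32371, 9250 of 13396), AttC (CG4744, 3636 of 8329) and Hr38 (CG2617, 250 of 274).

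**Figure D2:**
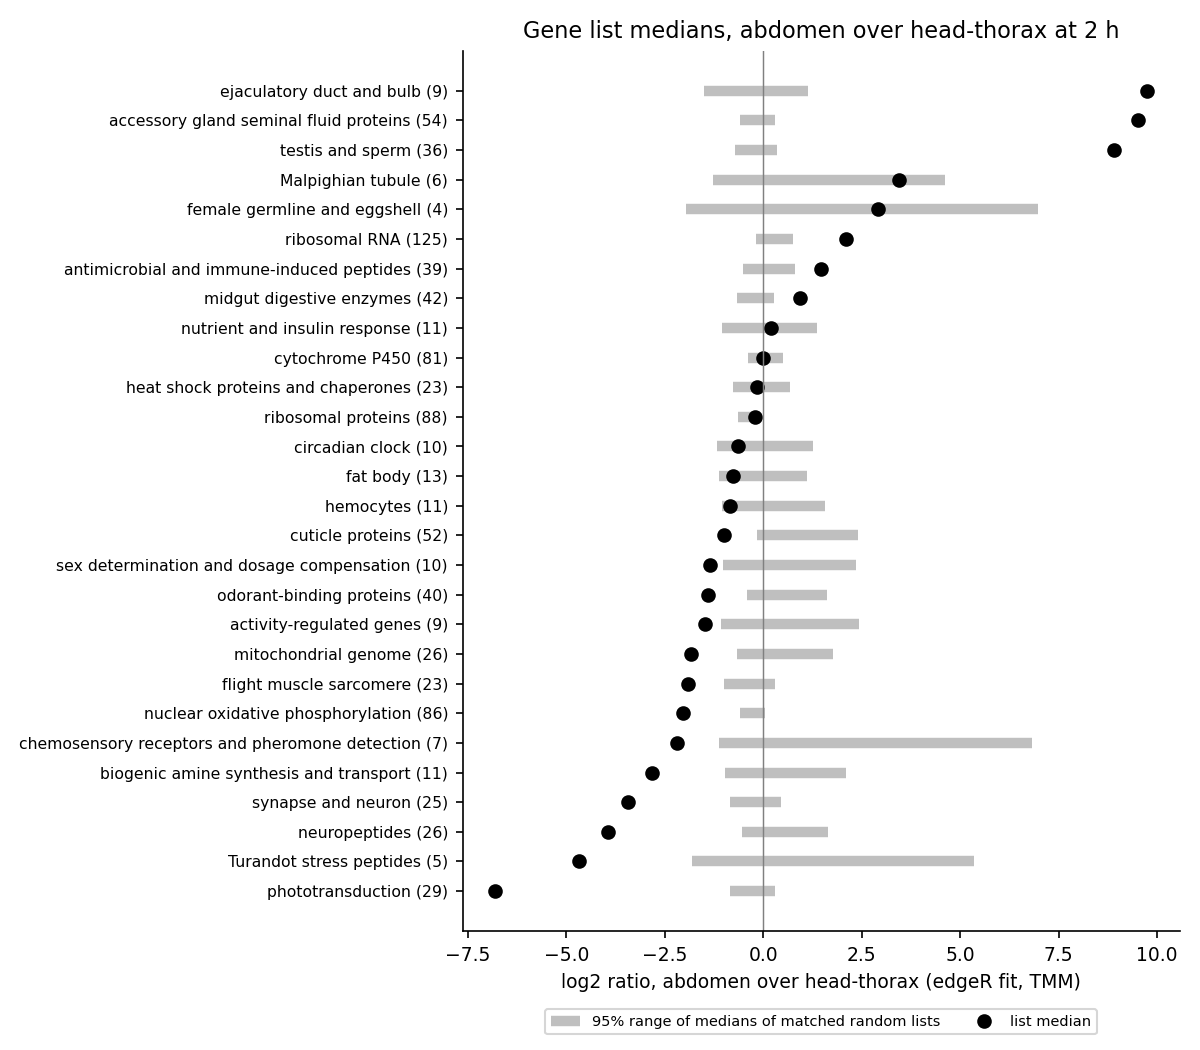
Median log2 ratio of abdomen over head-thorax at 2 h for each of the 28 gene lists (points, number of measured members in parentheses) with the central 95% of medians of matched random lists (bars). The ejaculatory, seminal fluid and testis lists stand highest, at 9.75, 9.51 and 8.90, and phototransduction lowest, at −6.81.

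The last comparison set head-thorax at 26 h with rivals against head-thorax at 2 h, the difference with length of exposure, at 1 pool per time. No pool was kept without rivals, so rival exposure was not separated from time itself. Turandot transcripts, which encode secreted stress peptides, were the most strongly lower group at 26 h. TotA fell from 1238 ± 17.9 to 130 ± 4.01 CPM and TotC from 559 ± 2.67 to 30.3 ± 0.421 CPM (SD, n = 2). By edgeR's quasi-likelihood test 912 of 14694 genes were higher at 26 h and 220 lower. Relative to TMM, DESeq2 size factors moved the median log2 ratio of all genes by 0.04 and raw totals by −0.10. Most of the genes that passed were rare: of those reaching at least 20 CPM in either pool, 26 were higher and 58 lower. With the fold tested inside the model, 317 were higher and 88 lower, and DESeq2's Wald test called 137 lower.

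All 5 measured Turandot genes were lower (median log2 ratio −4.21, or −3.52 with no filter on low counts, percentile 0.0), under each scaling tried. The ratios were −4.52 ± 0.10 SE for TotM (adjusted p = 2.6e-58), −4.21 ± 0.03 for TotC, −3.25 ± 0.03 for TotA and −2.59 ± 0.04 for TotX. TotB was scarce, at 0.949 CPM at 2 h and 2 counts at 26 h. In BDGP6.54 TotA lies at 20871036 to 20871700 on 3R and TotC at 20872988 to 20873580. Grik, a glutamate receptor gene (−2.04), overlaps TotX, so its reads and those of TotX cannot be separated. The peroxiredoxin genes Prx6c and Prx6b and the neighbouring CG12896, on 2R, were lower by −1.96 ± 0.05, −1.81 ± 0.04 and −1.87 ± 0.04, but Prx6b and CG12896 had close counts (6408 and 6401 at 2 h) and may share reads. The Y-linked ORY (−2.81) and kl-5 (−2.29) completed the rule-named lower genes. Both also differed between split libraries, ORY by 1.52-fold at 26 h and 1.22-fold at 2 h.

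**Figure D3:**
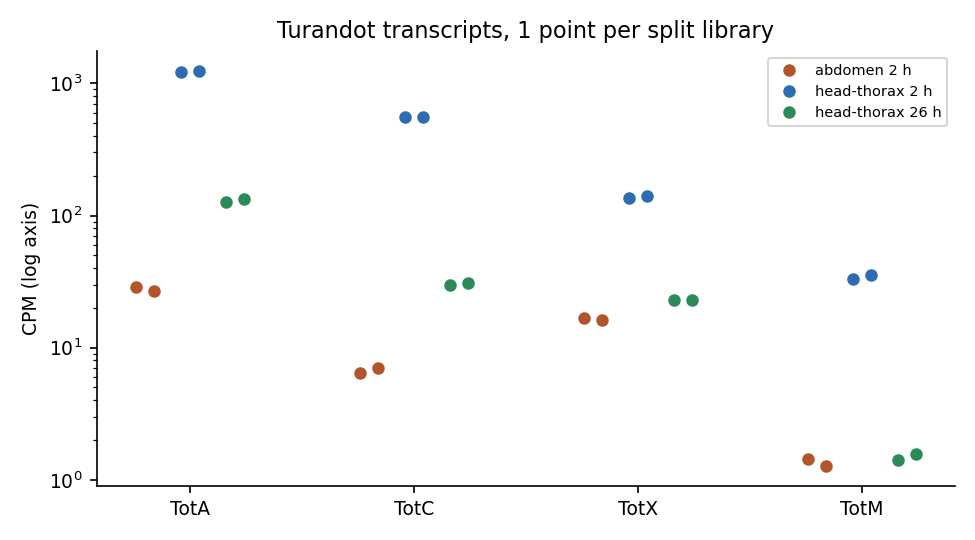
CPM (log axis) of TotA, TotC, TotX and TotM, with 1 point for each split library of each of the 3 pools. In each gene both 2 h head-thorax libraries lie above both 26 h libraries, for TotA at a mean of 1238 against 130 CPM.

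Among rule-named genes higher at 26 h were mt:ND6, a subunit of respiratory complex I, at 78.0 ± 8.57 against 21.6 ± 0.369 CPM (log2 ratio 1.86), the maltase Mal-A7 at 27.6 against 7.98 CPM (1.77), the mucin Muc11A (1.77) and phu (1.76). lncRNA:CR43960 (1.75) spans Muc11A and shares its reads, and CG44195 (1.41) overlaps Ank2. The remaining 4 named genes were copies of 5.8S ribosomal RNA with shared counts. The split libraries at 26 h differed for mt:ND6 (2039 and 2630 counts) and Muc11A (4204 and 5107 counts).

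Transcripts of abdominal organs rose in part, mostly at low level. The midgut list was not rare in head-thorax and did not rise in sum, at 11520 CPM at 2 h and 11500 CPM at 26 h. In the testis and sperm list 23 of 36 genes were higher and 0 lower (median 1.39, or 1.32 with bounds, percentile 100.0), but at low level. S-Lap1 was at a mean of 8.08 against 3.94 CPM, but its fitted ratio was just short of 2-fold. The ratio was past 2-fold under DESeq2 size factors (1.01) and by DESeq2's Wald test (1.06). It was also past it without split library 1 at 2 h (1.44) or split library 2 at 26 h (1.07). Of 42 midgut enzymes 13 were higher and 1, Jon25Bii, was lower (median 0.35, percentile 100.0), and Jon25Bii was short of 2-fold under DESeq2 size factors (−0.96), with the 4 libraries alone (−0.99), and without split library 1 at 2 h (−0.97) or split library 2 at 26 h (−0.99). In the ejaculatory list 3 of 9 were higher, Acp98AB, Dup99B and Obp51a (median 0.98, percentile 99.8). By adjusted p at any fold 6 members were higher and 2 lower, and in sum the list fell from 1769 CPM at 2 h to 1098 CPM at 26 h. Dup99B no longer passed without split library 2 at 26 h (log2 ratio 0.85), nor Obp51a without split library 1 at 2 h (0.94) or at 26 h (0.94). Of 54 seminal fluid genes 4 were higher, Sfp87B, Sfp60F, Acp33A and aqrs, or 2 when adjusted over the list alone (median 0.55, or 0.43 with bounds, percentile 78.6). Sfp87B was short of 2-fold under raw totals (0.95), and without split library 2 at 2 h (0.94) or split library 1 at 26 h (0.81). Acp33A did not pass without split library 1 at 2 h (1.34) or at 26 h (0.60). aqrs did not pass without split library 1 at 2 h (1.964), split library 2 at 2 h (1.22) or split library 1 at 26 h (1.12). With the fold tested inside the model none of these 4 passed, nor did Dup99B, Obp51a, NaPi-T, CapaR or Jon25Bii. Apart from cuticle proteins, where 4 in place of 3 were higher, counts adjusted over the list alone equalled those over all genes for the other lists. Of 6 Malpighian tubule genes 2 were higher, NaPi-T and CapaR (median 0.19, or 0.09 under raw totals and 0.76 over 4 with reads of their own, percentile 89.2), and CapaR did not pass without split library 1 at 2 h (1.35) or at 26 h (1.27). Over 177 abdomen-specific genes, split libraries 1 and 2 of head-thorax held 0.165% and 0.117% of the abdomen level at 2 h, and 0.317% and 0.249% at 26 h. These genes were chosen to be over 200 times higher in abdomen than in each head-thorax pool. The choice caps the percentages, so they do not measure the trace of abdomen transcripts in general.

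**Figure D4:**
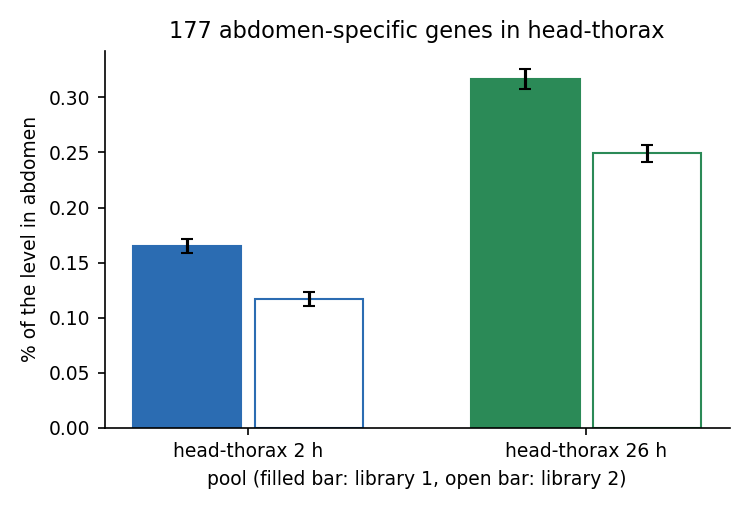
Summed CPM of 177 abdomen-specific genes in each head-thorax library, as a percentage of their level in abdomen, for split library 1 (filled) and split library 2 (open), with 95% counting intervals. Split library 1 is higher at both times, at 0.165% against 0.117% and at 0.317% against 0.249%. The genes were chosen to be over 200 times higher in abdomen than in each head-thorax pool, which caps the percentages.

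Of 11 hemocyte genes 10 were lower by adjusted p at any fold, and 2 passed the 2-fold limit as well (median −0.60, percentile 0.0). These were the prophenoloxidase PPO2 (−1.13) and the phagocytosis receptor NimC1 (−1.32), and the collagen Col4a1 was at −0.89 ± 0.03 SE. Of 39 immune peptides 2, BomS4 and BomBc1, were lower and 1, CecC, was higher (median −0.21, or −0.23 with bounds, percentile 0.0). CecC had 8 counts at 26 h and 0 at 2 h, at least 2.41-fold higher, and did not pass without split library 1 at 2 h (4.94) or split library 2 at 26 h (4.64). Of 13 fat body genes only the storage protein Lsp2 passed, at 374 against 971 CPM (list median −0.10, percentile 20.2). Heat shock genes had a median of −0.24 (percentile 0.0), with 1 of 23, Hsp60C, higher. In the P450 list 1 of 81, Cyp4g1, was higher, at 2467 against 988 CPM, while the median was −0.21 (percentile 0.0). Of 52 cuticle proteins 3 were higher, Cpr50Ca, Cpr56F and Cpr92A, and 2 lower, Acp1 and Lcp1 (median −0.25, or −0.28 with bounds, percentile 0.0). Over 37 cuticle proteins with reads of their own 1 was higher: Cpr50Ca and Cpr56F overlap S-Lap7 and CkIIbeta2, which held 299 and 12 counts at 26 h against their 324 and 15. Cpr50Ca was short of 2-fold under raw totals (0.96) and without split library 2 at 2 h (0.87). Cpr92A, with 5 counts at 26 h and 0 at 2 h, did not pass when any 1 of these 4 libraries was left out (3.98 to 4.64), nor without split library 1 of abdomen (4.39), nor with the split number as a block (4.31), DESeq2's Wald test (3.65) or no filter (4.35). Cpr56F did not pass without split library 2 at 2 h (1.38), or split library 1 (2.11) or 2 (2.06) at 26 h, nor Lcp1 without split library 1 at 2 h (−0.81) or at 26 h (−0.64), and neither passed by DESeq2's Wald test. With the fold tested inside the model none of these 5 cuticle proteins passed, nor did CecC or BomBc1.

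Neural and sensory genes differed little in size. None of 25 synapse genes passed the 2-fold limit (median 0.26, or 0.16 under raw totals and 0.08 over 7 with reads of their own, percentile 100.0). Of 40 odorant-binding proteins 3 were higher, Obp51a, Obp99a and Obp56f, all under 1 CPM, and 2 lower, Obp19b and Obp83g (median −0.23, or −0.12 with no filter on low counts, percentile 0.0). Without split library 2 at 2 h or split library 1 at 26 h, Obp99a (1.28 and 1.34) and Obp56f (1.499 and 1.27) did not pass, nor did Obp51a without split library 1 of either pool (0.94 and 0.94). Of 26 neuropeptides 1, Ilp3, was lower (median 0.04, turning to −0.06 under raw totals, percentile 88.4), and it did not pass without split library 1 at 2 h (−0.85). In phototransduction 1 of 29, the scavenger receptor ninaD, was lower (median −0.12, percentile 3.4). Of 7 chemosensory genes 1, ppk23, a channel gene of pheromone-sensing neurons, was lower (median −0.10, turning to 0.04 with no filter on low counts, percentile 17.5). With the fold tested inside the model ppk23 (−1.37), Ilp3, Obp51a, Obp99a, Obp56f and Obp19b did not pass, and Obp56f also did not under raw totals (2.09) or DESeq2's Wald test (2.36). None of the 11 biogenic amine genes (median −0.13, percentile 13.3), 10 circadian genes (−0.06, 36.2), 9 activity-regulated genes (−0.12, 20.8), 10 sex determination genes (−0.03, 50.4) or 4 eggshell genes (0.23, or 0.16 with bounds, 26.4) passed. The male courtship regulator fru was at −0.01 ± 0.04 SE and dsx at 0.02 ± 0.03, and under raw totals at −0.11 and −0.08, where both passed the adjusted p threshold but not 2-fold.

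Of the nutrient response list 1 of 11, Lip3, was higher (median −0.04, percentile 45.5). Of 23 muscle genes 1, Msp300, was higher, at 1207 against 487 CPM (list median −0.14, percentile 4.5). In the mitochondrial genome 6 of 26 were higher and 1, mt:tRNA:Leu-TAG, lower (median 0.21, percentile 98.8), with mt:lrRNA at 0.64 ± 0.04 SE. mt:tRNA:Leu-TAG did not pass without split library 1 at 2 h (−1.55) or split library 2 at 26 h (−1.38). Nuclear oxidative phosphorylation had 2 of 86 higher, ATPsynbetaL and ND-51L2 (median −0.08, or −0.09 with bounds, percentile 0.7), and ribosomal proteins 6 of 88 (median −0.05, percentile 15.4). ND-51L2, with 6 counts at 26 h and 0 at 2 h, did not pass without split library 1 (4.54) or 2 (4.66) at 2 h or split library 1 at 26 h (4.53). With the fold tested inside the model ND-51L2, Lip3 and mt:tRNA:Leu-TAG did not pass, nor mt:tRNA:Leu-TAG by DESeq2's Wald test (−1.73). The ribosomal RNA list held 105 higher and 13 lower of 125, again mostly copies that share reads (median 2.15, percentile 100.0), with 18SrRNA:CR45838 at −1.68. Of the 21 with reads of their own 8 were higher and 6 lower, at a median of −0.02. Among genes named at 26 h, Lsp2, Msp300, Cyp4g1, BomS4, Cpr50Ca, Cpr56F, Ilp3, Lip3, Sfp87B, Acp33A, Obp51a, ND-51L2, RpS10a and dsx overlap another gene and may hold its reads.

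The genes higher at 26 h overlapped with those higher in abdomen. Of the 912 genes higher at 26 h, 862 were also higher in abdomen than in head-thorax at 2 h, where independent lists would share 324.8. Both comparisons use the same 2 h head-thorax libraries. Simulated unchanged pools, which carry technical spread only, gave 0 shared calls. The covariance of the log2 ratios was 1.76 against a simulated 0.02. Unchanged pools give almost no calls in either comparison, so both simulated values bear on technical spread alone. With split library 1 as the control at 26 h and split library 2 as the control for abdomen, 571 of 629 were shared, against 222.4 for independent lists. Both controls come from 1 pool, so a deviation of the 2 h head-thorax flies would be shared by both comparisons, and part of the excess may come from it. The filter on low counts used all 6 libraries, so a gene rare in head-thorax could be tested through its abdomen level alone. Only 365 of the 912 genes reached 1 CPM in either head-thorax pool. The counts for independent lists do not allow for this filter, which may give another part of the excess.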

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

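All tests of explanations weighed here, and the bounds set on them, were chosen after the results they bear on had been seen at least in part; leaving out 1 library and the other scalings had been planned as alternatives for every comparison.

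The mitochondrial coding transcripts differed between the split libraries of each pool. Summed over 13 coding genes the log2 ratio of split library 1 to split library 2 was 0.12 in abdomen (95% counting interval 0.119 to 0.128), −0.07 in head-thorax at 2 h (−0.0705 to −0.0656) and 0.05 at 26 h (0.0441 to 0.0484). The difference was 0.19 between abdomen and head-thorax at 2 h and 0.11 between head-thorax at 26 h and at 2 h, with counting intervals that do not meet. The numbers 1 and 2 did not pair the libraries across pools, so the sign of each ratio depends on the numbering. These differences are therefore not read as differences between pools. Abundant genes varied by more than counting error between split libraries, so the intervals are too narrow for that spread. Averaged over genes the ratios were 0.12, −0.06 and 0.01, the last with an SD of 0.08 over genes, where 11 of 13 were higher in split library 1 and mt:ND6 went the other way (−0.22). The test is of reads, not of replicate pools.

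Abdomen-specific transcripts appeared at unequal trace levels in the split libraries. Over 177 genes (at least 50 CPM in abdomen, over 200 times their head-thorax level, with no overlap and no identical counts), head-thorax at 2 h held 0.165% of the abdomen level in split library 1 and 0.117% in split library 2, a ratio of 1.41 (95% interval over genes 1.30 to 1.52), or 1.412 without Met75Ca and Met75Cb, which have near-identical counts. At 26 h the ratio was 1.27, and 22 head-specific genes in abdomen gave 1.75. Tissue carried in at dissection would put equal shares in both libraries, a ratio near 1, whereas reads assigned to a library after the split may follow the abdomen level of each gene. The ratio lies outside the range of 0.9 to 1.1 set for carried tissue but short of the 1.5 set to exclude it. The excess had a Spearman rho of 0.371 with abdomen level across genes, short of the 0.5 set for assigned reads. On these bounds the sources of the trace cannot be told apart, and both may contribute to its level. The intervals over genes, also 1.21 to 1.33 at 26 h and 1.31 to 2.09 in abdomen, lie above 1.1. The 177 genes gave 0.996 between the abdomen libraries. For these genes, the values argue against carried tissue as the only source of the inequality.

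Genes higher at 26 h were mostly rare, and 862 of 912 were also higher in abdomen, which carried abdomen tissue would give. The filter on low counts, applied over all 6 libraries, may also add to this share. The tables argue against whole abdomen tissue carried into the 26 h pool as the sole source, since the excess at 26 h was 0.0657% of the abdomen level for 30 seminal fluid genes (counting interval 0.0469 to 0.0845), 0.322% for 18 testis genes (0.297 to 0.347) and 3.75% for 8 midgut enzymes, over members with reads of their own, at least 20 CPM in abdomen and over 10 times their 2 h head-thorax level. The highest was 57.1 times the lowest, where carried tissue predicts alike values within 3 times, and the testis and seminal fluid intervals alone lie over 3 times apart. The midgut list as a whole was abundant in head-thorax, at 11520 CPM at 2 h, so its share need not measure carried tissue. The choice of scaling made little difference, as 816 genes stayed higher under raw totals, the lower count of the 2 scalings. Raw totals and DESeq2 size factors move the median of all genes by only −0.10 and 0.04, so a larger scaling difference was not tested. A piece of 1 organ and an effect of the longer exposure stay open, untested, because each time is 1 pool. Abdomen reads assigned to a library after the split also stay open as a part of the excess. The trace of abdomen-specific genes at 26 h was unequal, at 0.317% in split library 1 and 0.249% in split library 2.

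Turandot transcripts were lower at 26 h. The choice of scaling made little difference. Raw totals or DESeq2 size factors moved no called member by more than 0.0971 on the log2 scale, against a median of −4.21. These scalings move all genes by about the same small amount (−0.10 and 0.04 at the median), so a larger scaling difference was not tested. Reads from 1 library only are argued against, since leaving out 1 library moved the median of −4.21 by at most 0.0143. A difference between these particular pools of flies and an effect of exposure time stay open, because time and pool coincide. An effect of rivals cannot be separated from time itself, since every pool was kept with rivals.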

How the results depend on the processing

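The alternatives restricted to genes without overlap, and those without mitochondrial, ribosomal RNA or near-identical genes, including the trace genes, were chosen after seeing the data. In abdomen against head-thorax, counts stayed within 1.5 times of 5233 higher and 3194 lower genes under DESeq2 size factors, raw totals, DESeq2's Wald test, no filter, 4 libraries and glmTreat. With no fold threshold 6412 were lower. Only genes that overlap no other gave 2836 higher and 1669 lower, since fewer genes were tested. Leaving out each library gave 5008 to 5454 higher and 3012 to 3251 lower. In 26 h against 2 h, no fold threshold gave 2895 higher and 3123 lower, glmTreat 317 and 88, DESeq2's Wald test 137 lower, and genes without overlap 554 and 112. Leaving out 1 head-thorax library changed which genes were called at 26 h as well as how many. Some genes of each list were then not called. A pool left with 1 library is assumed to vary like the others. With the split number as a replicate block, 5222 and 3195 genes were higher and lower in abdomen and 891 and 190 at 26 h. Over 7459 genes with ample counts in every library, the numbers did not pair the libraries, with correlations of same-numbered deviations of −0.0586, 0.0384 and −0.0258. The trace genes of the other body part were too rare for this check. They were higher in split library 1 in every pool, by 1.41 and 1.27 in head-thorax at 2 h and 26 h and 1.75 in abdomen.

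Between split libraries, genes without overlap and outside the mitochondrial, ribosomal RNA and near-identical sets that differed numbered 103 in abdomen, 15 in head-thorax at 2 h and 16 at 26 h. Without mitochondrial and near-identical genes the variance over counting error was 1.68, 1.33 and 1.255. At 10 counts or more, split libraries 1 and 2 held 94.55% and 96.99% of the genes of the sum in abdomen, 95.7% and 92.1% in head-thorax at 2 h, and 93.4% and 93.7% at 26 h. Thinned to the smaller library, the shares were 97.9% and 97.8% in abdomen, 95.95% and 95.1% at 2 h, and 96.4% for split library 2 at 26 h. By fold and mean count with no test, split libraries 1 and 2 gave 90.85% and 92.3% of the abdomen calls, and 1 gene was called in opposite directions in the 26 h comparison. The median of cuticle proteins in abdomen turned to 0.0568 with no filter. The cause of these moves was not tested beyond the smaller number of genes. Of 3051 alternatives for 211 named-gene values, 2953 kept their side of the adjusted p threshold, fold aside, 94 lost it and 4 gained it (at 26 h, fru and dsx under raw totals and cpx under raw totals and DESeq2 size factors), and no called value changed sign past the threshold (0). Of these dsx and cpx changed sign under raw totals, to −0.08 and −0.07. Calls from 1 library missed genes with a median summed count of 21 or 23 in the abdomen comparison and 29 or 31 at 26 h.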

Other observations

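The observations here were chosen after the values were seen. Prx6c, Prx6b and CG12896, 3 neighbouring genes on 2R in BDGP6.54, were each lower at 26 h, at 71.9, 119 and 119 CPM at 2 h against 18.5, 33.99 and 32.5 CPM. Prx6b and CG12896 had close counts and may share reads, so they may not be separate observations. The 6 ribosomal protein genes higher at 26 h, RpL22-like, RpS5b, RpS19b, RpS10a, RpL10Aa and RpL37-2, were each below 1 CPM there, and all but RpL22-like lost the call when a single library was left out. These losses were RpS5b without split library 2 at 2 h (0.68) or at 26 h (1.096), RpL10Aa without split library 1 at 2 h (2.35), and RpL37-2 without split library 1 at 2 h (2.26) or at 26 h (2.46). RpS19b lost it without split library 2 at 2 h (1.08), or split library 1 (1.62) or 2 (1.48) at 26 h, and RpS10a without any single one of the 4 libraries (1.56 to 2.53). With the fold tested inside the model only RpL22-like passed, and by DESeq2's Wald test RpS10a (1.99) and RpS19b (1.63) did not. RpS10a, with 17 counts at 26 h, overlaps tau, with 7078, and may hold its reads. In the mitochondrial genome mt:ND6 was higher at 26 h by a log2 ratio of 1.86 ± 0.05 SE, while mt:CoIII, which overlaps another gene, stood at 0.02 ± 0.03.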
